A study of Mus musculus with 4 samples.

How the data were processed

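Peritoneal immune cells of wild-type mice, collected by lavage and sorted for the leukocyte surface protein CD45, were profiled by droplet single-cell RNA sequencing and by sequencing of B-cell receptors (BCR). The diet groups, CD for chow and HFD for high-fat feeding, lasted 3 months from an age of 4 weeks. Each diet has 1 expression library and 1 receptor library. The labels give neither the number of mice nor whether mice were pooled. A treatment note in the labels places both groups on the high-fat diet; the groups used here are those of the sample titles and of the series design, which names chow for CD.

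The deposited expression files hold counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, and per the file headers they were written by Cell Ranger 8.0.1. The submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.3.0 and genome build mm39, so the version that made the matrices differs between header and notes. The settings of cell calling and any later filter are not stated. The deposited receptor tables hold counts of UMIs and reads per contig, with text annotation of V, J and constant genes and of CDR3 sequences; all 18797 contigs of the CD library and all 8706 of the HFD library are listed as productive. Gene symbols are those of the feature files, which list 33696 genes; 17 symbols stand on several gene identifiers.

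The CD matrix holds 13227 barcodes and 73549582 UMIs, with a median of 4416 UMIs and 1619 genes per barcode. The HFD matrix holds 6897 barcodes and 57630074 UMIs, with a median of 6298 UMIs and 2051 genes. Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run on each library, called 0 of 13069 CD barcodes and 5 of 6684 HFD barcodes as doublets, or 0.0748%. A rate this low at such barcode numbers means that the tool did not find the doublets, and barcodes of mixed content remain. After removal of those 5 barcodes, 13069 CD and 6679 HFD barcodes were analysed. Xist gave 0 UMIs and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d gave UMIs in both libraries.

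Counts were scaled to 10000 UMIs per barcode and log-transformed. Both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 28 clusters. Receptor, mitochondrial and ribosomal protein genes were left out of the variable genes. Clusters were named from marker lists fixed before the data were examined, and a name ending in "like" means that the markers of that type led. For B-like clusters, the mean log2 level of B1 markers less that of B2 markers was centred on the midpoint of its extremes. Clusters more than 0.5 above that midpoint were called B1-like, those more than 0.5 below it B2-like, and the rest B-intermediate. The midpoint comes from the clusters named together, so it can differ between settings with new clusters. Clusters with markers of several lineages above a score of 0.9 were called mixed-lineage, and 1 macrophage cluster with markers of large and small peritoneal macrophages was left unnamed. The limits of 0.5 and 0.9 were set after the data were seen.

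Shares of barcodes carry exact Clopper-Pearson 95% intervals, and differences carry Newcombe intervals. Within a class, UMIs were summed per library and expressed as CPM, the count per 1000000 UMIs of the sum. The log2 ratio of HFD over CD carries the exact conditional interval of a ratio of Poisson counts. With 1 library per diet, no test between diets is possible, no p-value is given and barcodes are not treated as replicates. All intervals cover counting error only, and differences between mice or preparations are not in them. Classes with at least 100 barcodes in each library were compared, which gave 6 classes.

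Named genes follow a rule fixed before the data were examined. In each class it takes genes at 30 CPM or more in the higher library, with 50 UMIs or more over both sums, found in at least 10% of barcodes, and at no less than 10% of their highest level over all classes. It takes the 10 highest and 10 lowest ratios in the 4 main classes and fewer in other classes, and not every gene it takes is printed. Receptor segments, mitochondrial, ribosomal protein and sex-linked genes were left out. The 28 gene lists were fixed at the same time. A list is given as the median log2 ratio of its members with 20 UMIs or more, with an interval from 1000 Poisson resamplings, and as its percentile among 10000 random lists matched on expression, which only describes these libraries. Up to 4 members per list, those of largest absolute ratio, are given as examples.

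Receptor analysis used barcodes with exactly 1 productive heavy and 1 productive light contig: 6536 in CD and 3225 in HFD. A clonotype is the same V gene, J gene and CDR3 nucleotides in both chains. Clone measures were compared after drawing 3225 CD barcodes 1000 times. Of the barcodes in the receptor tables, 78.5% of CD and 89.4% of HFD lay in the matrix of the same diet, against 0.231% and 0.557% in the matrix of the other diet, so receptors were joined to expression by barcode.

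Alternatives fixed in advance were looser and stricter barcode filters, kept doublets, Leiden resolutions of 0.5 and 2, clustering of each library alone, thinning of every barcode to 2200 UMIs, edgeR TMM and median-of-ratios scaling, equal weight per barcode, other count minimums for list members, and other contig and clonotype definitions. Chosen after the data were seen were the removal of 2-lineage barcodes, with or without the mixed-lineage clusters or with clusters drawn anew, the merging of B1-like and B-intermediate barcodes, B-intermediate clusters given to the side their markers lean to, counting each clonotype once, and subtraction of a B-like RNA profile in macrophage-like and T-like cells. A 2-lineage barcode reached 25% of the median marker share of another lineage's own classes or carried a receptor contig outside the B-like classes. The B-like profile is the summed expression of the B-like classes of the same library, and its share in a class was taken from B marker genes other than immunoglobulin genes.

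The methods were tested on simulated data drawn from the mean profile of all barcodes of both libraries. Of 11517 simulated ratios, 95.5% lay in their intervals. Of 50 changed genes each at folds of 0.25, 0.5, 2 and 4, the intervals left 0 for 100%, 96%, 98% and 100%. Of 50 lists without a change, 8% lay outside the 2.5th to 97.5th percentile. For the subtraction, that same mean was mixed in as the profile, in place of the profile of the B-like classes. Where only its share differed, it accounted for 122% of a fall, and where only the genes differed, for -0.585%. The subtraction as applied to the data was therefore not tested. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, R 4.3.3 and edgeR 4.0.16.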

Results

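Peritoneal CD45-sorted cells of chow-fed (CD) and high-fat-fed (HFD) mice were compared for the make-up of the cell classes, for expression within classes and for B-cell receptors. Each diet is 1 library, so the differences below are differences between 2 libraries, and every interval covers counting error only.

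In both libraries most barcodes were B-like, with large-macrophage-like and T-like cells next. Large-macrophage-like cells, the resident population of the cavity, made up 16.6% of barcodes in CD and 21.2% in HFD, a difference of 4.56 points (95% interval 3.40 to 5.74). T-like cells were 7.11% in CD and 10.8% in HFD. B-like cells of all kinds were 63.5% in CD and 59.1% in HFD, a difference of -4.34 points (-5.78 to -2.90). Within them, B2-like cells, the conventional B cells, were 13.9% and 17.6%. B1-like cells, the innate-like B cells typical of this cavity, were 18.4% in CD and 29.6% in HFD, while B-intermediate cells, with markers of both, were 31.2% and 12.0%. Cluster 0, which leaned to the B1 side, held 76.3% of B-intermediate barcodes in CD and 75.3% in HFD. B-intermediate barcodes were shallower than B1-like ones, with medians of 3523.5 against 7290 UMIs in CD and 4419 against 8426 in HFD. Taken as 1 class, B1-like and B-intermediate cells were 49.6% in CD and 41.6% in HFD, a difference of -8.03 points (-9.48 to -6.56), so the direction for B1 cells rests on where the line between these clusters is drawn. The same holds for B2-like cells. With each B-intermediate cluster given to the side its markers lean to, chosen after the data were seen, B2-like cells were 21.3% in CD and 20.5% in HFD, a difference of -0.74 points (-1.93 to 0.46), and B1-like cells 42.2% and 38.6%.

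Over the planned settings the B1-like difference ranged from -3.32 points, with at least 800 genes and at most 5% mitochondrial UMIs per barcode, to 25.7 points, with each library clustered alone. Shares are of CD45-sorted cells past the filter and say nothing of cell numbers, and median depth differed, at 4464 UMIs per kept barcode in CD and 6452 in HFD.

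Smaller classes differed less in points. Gamma-delta-T-like cells were 1.63% in CD and 0.749% in HFD, NK-like cells 0.260% and 0.749%, and cDC2-like dendritic cells 1.88% and 1.21%. For cDC1-like dendritic cells, at 0.230% and 0.195%, no difference was detectable at this depth (-0.16 to 0.12 points). Small-macrophage-like cells were 2.26% and 1.42%, but were higher in HFD by 1.41 points with each library clustered alone. The unnamed macrophage cluster was 3.37% in CD and 2.34% in HFD, with no difference detectable without 2-lineage barcodes (-0.85 to 0.10 points), and the mixed-lineage clusters were 3.17% and 2.20%.

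**Figure D1:**
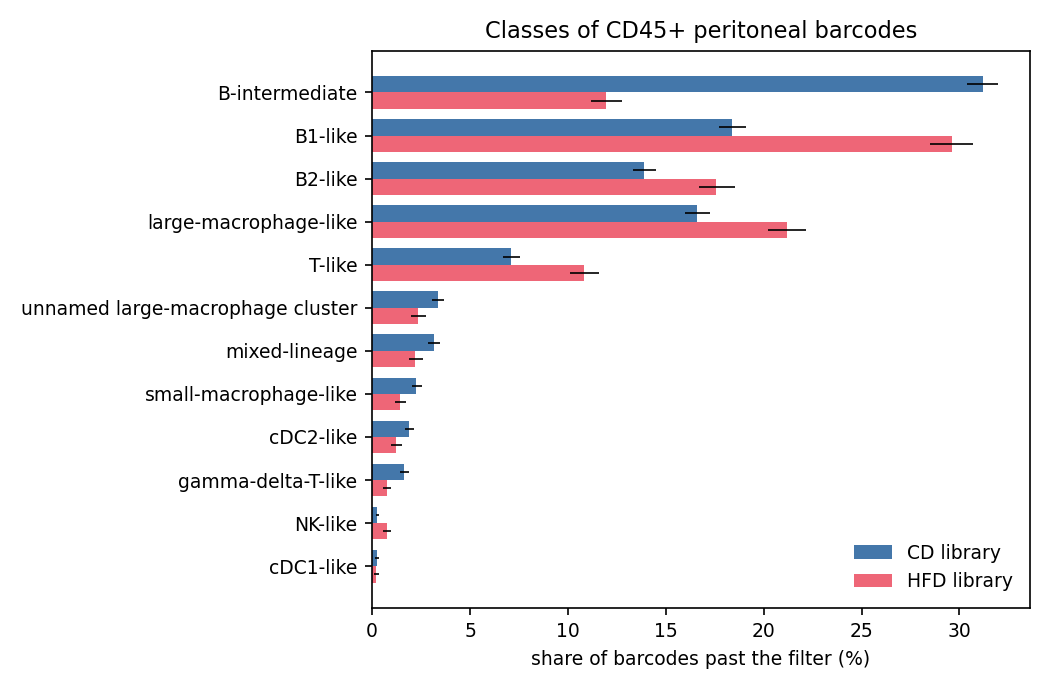
Share of barcodes past the filter (%) in each class for the CD and HFD libraries, with exact 95% binomial intervals that cover counting error only. B-intermediate barcodes were 31.2% in CD and 12.0% in HFD, and large-macrophage-like barcodes 16.6% and 21.2%.

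In large-macrophage-like cells Marco, Cxcl13 and Apoe were among the genes with the lowest ratios. Marco, a scavenger receptor, was at 75.0 CPM in CD and 7.30 in HFD, a log2 ratio of -3.36 (-3.62 to -3.11), and Cxcl13, the chemokine that draws B cells, was at 3968 and 542 CPM, a log2 ratio of -2.87 (-2.90 to -2.84). The apolipoprotein gene Apoe was at 14644 and 3329.9 CPM, 4.40-fold lower. The monocyte-attracting chemokines Ccl2 and Ccl7 were higher in HFD, with Ccl2 at 12.6 and 62.2 CPM (log2 2.30; 2.08 to 2.54) and Ccl7 at a log2 ratio of 2.37. All 26 measured cell cycle genes were higher, with a median log2 ratio of 1.34 (1.17 to 1.44).

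Further genes among the 10 lowest were F13a1, the A subunit of coagulation factor XIII (-3.04), Cd38, an NAD-consuming ectoenzyme (-2.94), Stab1, a scavenger receptor (-2.20), and Fscn1, an actin-bundling protein (-2.18). Ets1, a lymphocyte transcription factor (-2.36), Fcrla, a B-cell Fc receptor-like gene (-2.14), and Acp5 (-2.09) were also among them, but a B-like profile accounted for 80.4%, 111% and 98.7% of their CPM in CD. Among the 10 highest were Klk8, a secreted serine protease (2.42), Emb, an immunoglobulin-family adhesion protein (2.28), Car6, a carbonic anhydrase (1.87), Stmn1, a microtubule-destabilizing protein (1.79), S100a4, a calcium-binding protein (1.74), Mcm5, part of the replicative helicase (1.74), Emp1 (1.72) and Tppp3 (1.67). After subtraction of the B-like profile, chosen after the data were seen, the 17 other genes kept their direction. None of them could have turned. Each had under 50% of its CPM from the profile in both libraries, and a log2 ratio of at least 1.67 in size. Of the 124 genes of this class that met the naming rule and differed by 1 log2 unit or more, 41 had 50% or more of their CPM from the profile in at least 1 library.

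**Figure D2:**
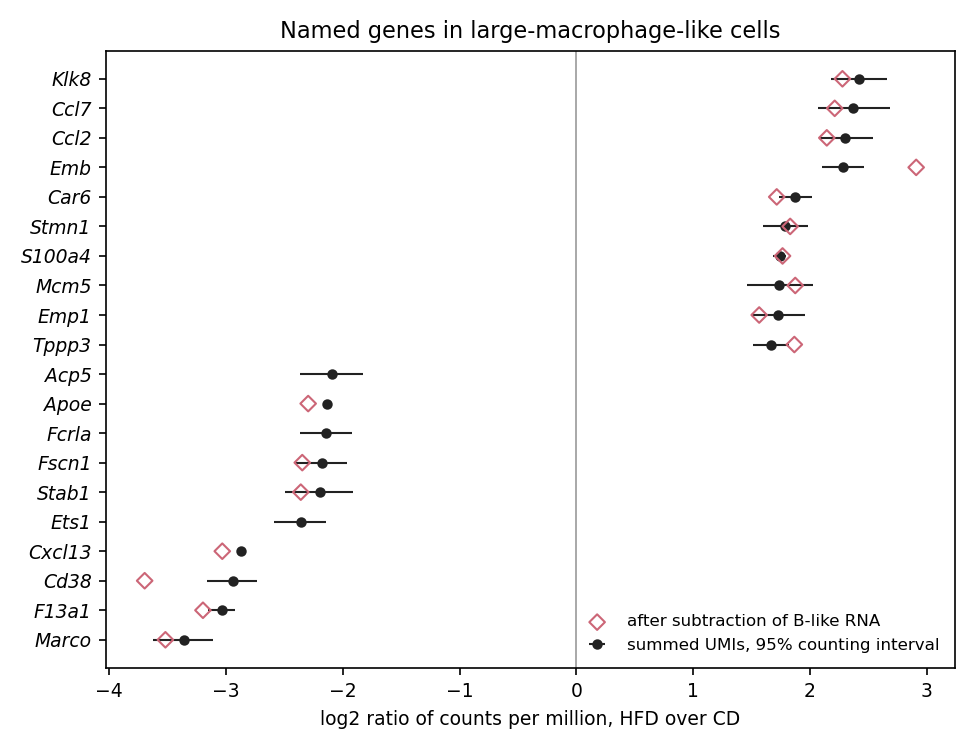
Log2 ratio of CPM, HFD over CD, of the 20 named genes in large-macrophage-like cells. Filled points are ratios of summed UMIs with 95% counting intervals, and open diamonds are ratios after subtraction of a B-like profile, drawn for the 17 genes with less than 50% of their CPM from it; values run from -3.36 for Marco to 2.42 for Klk8.

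Lipid handling and inflammatory genes were the main lists for these cells. Lipid handling genes had a median log2 ratio of 0.09 (0.03 to 0.16), with 16 of 28 measured members above 0, and the median was -0.06 after subtraction of the B-like profile. No shift was detectable with each library clustered alone (-0.003 to 0.12) or without 2-lineage barcodes (-0.02 to 0.16). Its members went both ways, from Apoe to Spp1, the secreted phosphoprotein osteopontin, at 2.73, Angptl4, an inhibitor of lipoprotein lipase, at 1.22, and the lipid droplet gene Hilpda at 1.04. Inflammatory NF-kB genes had a median of 0.12 (0.02 to 0.19), or 0.25 thinned to equal depth and 0.10 (-0.01 to 0.18) at 800 genes and 5% mitochondrial UMIs, with Ccl2 and Ccl7 at the top and Cd83 (-1.60, or -1.01 without 2-lineage barcodes) and Socs3, a brake on cytokine signalling (-1.27), at the bottom.

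Several other lists lay at the ends of the random lists. Interferon response genes had 27 of 30 members below 0 and a median of -0.62 (-0.70 to -0.50), or -0.40 thinned to equal depth, among them Ly6a (-1.96) and Ifi209 (-1.29). Without 2-lineage barcodes Ly6a was at -1.13 and Ifi209 at -0.86, and after subtraction of the B-like profile, which left out 4 members as mostly B-like RNA, the median was -0.52. Complement and coagulation genes had a median of -0.39, with Cfb, complement factor B, at -1.50 and C4b at -0.97, but F7, coagulation factor VII, at 0.82. Efferocytosis and scavenging genes had a median of -0.29, or -0.44 after subtraction of the B-like profile. Thinned to equal depth the median was -0.14 (-0.31 to 0.03), where no shift was detectable. The list included Timd4, the phosphatidylserine receptor of resident macrophages, at -1.33. Glucocorticoid targets had a median of -0.90, with 12 of 13 below 0 and Fkbp5 at -1.67, and heat shock genes a median of -0.44, with Hspa8 at -0.79 and Dnajb1 at -0.86. All 15 MHC class I genes were below 0, with a median of -0.33. The alternative activation list had a median of -0.85, but -0.45 after subtraction of the B-like profile. No shift was detectable at 800 genes and 5% mitochondrial UMIs (-0.23; -0.45 to 0.04), at 200 genes and 20% (-0.25; -0.40 to 0.15) or thinned to equal depth (-0.29; -0.49 to 0.12). Among its members Mgl2, a lectin, was at 1.88 and the transcription factor Klf4 at 1.18.

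Energy metabolism genes were slightly higher in HFD. Glycolysis genes had a median of 0.25 (0.21 to 0.33), with Gapdh at 0.70 and the lactate transporter Slc16a3 at 0.81. Oxidative phosphorylation genes had a median of 0.21, with 25 of 28 above 0, and fatty acid oxidation genes a median of 0.18, or 0.11 without 2-lineage barcodes, led by Pdk4, an inhibitor of pyruvate dehydrogenase, at 2.95. Of the cell cycle genes, the mitotic kinase gene Cdk1 was at 2.32 and Rrm2, of the ribonucleotide reductase, at 2.30. The resident macrophage list had a median of 0.10, but 0.03 (-0.002 to 0.07) without 2-lineage barcodes and -0.058 after subtraction of the B-like profile, with Saa3, an acute-phase protein, at -1.82 and Cxcl13 below it.

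MHC class II genes were lower in all 11 members, with a median of -1.59 (-1.64 to -1.45). B-cell RNA moved with them: it made up 14.5% of the class's UMIs in CD and 4.46% in HFD, and 15.2% and 4.53% of barcodes carried a receptor contig. Different clusters held the class in the 2 libraries: clusters 4 and 6 held 49.1% and 47.0% of the CD barcodes, and clusters 5, 21 and 23 held 74.3%, 11.3% and 7.64% of the HFD barcodes. Cluster 23, whose leading genes include Ccnb2 and Birc5, held 1.24% of the CD barcodes. Median depth in the class was 4873 UMIs in CD and 12374.5 in HFD.

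In B1-like cells, heat shock and unfolded protein response genes, which include many chaperones, were lower in HFD, and so were Cd69, Tagap and Myc. Cd69, an early activation receptor, was at 88.6 CPM in CD and 27.9 in HFD, a log2 ratio of -1.67 (-1.82 to -1.52), and Tagap was at -1.70. Myc, the growth transcription factor, was at -0.99 (-1.08 to -0.89). Tppp3, a tubulin-binding protein, was the highest of the named genes, at 103 and 431 CPM, a log2 ratio of 2.06 (1.99 to 2.13). It is also a B1 marker of the lists used to name the clusters. Cluster 15, whose leading genes include Tppp3, D130009I18Rik and Lars2, held 2.25% of the B1-like barcodes in CD and 13.5% in HFD. Cluster 25, with H2ac24 among its leading genes, held 1.33% and 2.23%. The part of this make-up in the ratios of these genes was not tested.

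Other low genes were Ankrd37 (-1.40), Gm26532 (-1.26), Rsrp1 (-1.16), Ly6k (-1.13), Gadd45b, a stress-induced gene (-1.13), and Chchd10, a mitochondrial protein (-1.08). The other high genes were the histone gene H2ac24 (1.35), D130009I18Rik (1.19), Gm43305 (1.17), Ptms (1.17), the interleukin-9 receptor Il9r (1.16), Crip2 (1.12), Lars2, the mitochondrial leucyl-tRNA synthetase (1.09), Pard3b (1.06) and Sapcd1 (1.05). Heat shock genes had a median of -0.64 (-0.68 to -0.52), with 11 of 12 below 0, and Hsph1 at -1.18. Unfolded protein response genes had a median of -0.33 (-0.43 to -0.29), with 16 of 18 below 0; Hspa5, the main endoplasmic reticulum chaperone, was at -0.75 and Hsp90b1 at -0.58.

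The B-cell activation list had a median of -0.02 (-0.09 to 0.05), with 10 members above 0 and 10 below, but -0.34 with each library clustered alone, and the immediate early list a median of -0.04 (-0.09 to 0.01), so no shift of either was detectable in the main setting. With each library clustered alone Chchd10 was at -0.10, Sapcd1 at 0.45, Pard3b at 0.58, Ly6k at -0.74 and Gadd45b at -0.66, Il9r was at 0.73 thinned to equal depth, and at 200 genes and 20% mitochondrial UMIs D130009I18Rik was at 0.21 and Lars2 at 0.32.

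Antibody secretion, the main list for this class, had a median of 0.03 (-0.02 to 0.07), so no shift of the list was detectable. Its members went apart, with Jchain, which joins IgM pentamers, at 2.25, Prdm1, the plasma cell regulator, at 1.47, and Fkbp11 at -0.81. All 26 cell cycle genes were above 0, with a median of 0.76 (0.62 to 0.90) and Mki67 at 1.36, but with each library clustered alone the median was 0.10 (-0.004 to 0.19) and no shift was detectable. Fatty acid oxidation, inflammatory and interferon response lists had medians of 0.20, 0.28 and 0.24; thinned to equal depth, the first was 0.07 (-0.02 to 0.19) and the last 0.08 (-0.05 to 0.14), so neither shift was detectable there. Nor was the interferon shift detectable at 800 genes and 5% mitochondrial UMIs (0.04; -0.02 to 0.16), at 200 genes and 20% (-0.01 to 0.14) or with doublets kept (-0.004 to 0.19), and the inflammatory median was 0.16 with equal weight per barcode. The regulatory and innate B-cell list had a median of 0.24, with Il12a at 1.49, but no shift was detectable with each library clustered alone (-0.01; -0.08 to 0.16) or with doublets kept (0.10; -0.02 to 0.21). The resident macrophage list, genes of another cell type, had a median of 0.68 in these cells. Macrophage RNA was not subtracted, so its part in the other lists was not tested.

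B2-like cells shared part of the pattern. Cd69 was at -1.27 (-1.40 to -1.15), Tagap at -1.20 and Rsrp1 at -1.25, and the heat shock list had a median of -0.47 (-0.58 to -0.39) with 9 of 10 members below 0. Cxcr4, the chemokine receptor for CXCL12, was the lowest named gene, at 50.5 and 15.7 CPM, a log2 ratio of -1.68 (-2.03 to -1.35). It was also lower in B1-like (-1.20), B-intermediate (-1.83), T-like (-0.87) and large-macrophage-like cells (-3.17). The heat shock median was below 0 in every class compared, at -0.59 in B-intermediate cells and -0.38 in the unnamed macrophage cluster. A difference of the whole libraries was not told apart from one of B cells. Camk2b, a calcium-dependent kinase, was the highest named gene, at 1.48 (1.15 to 1.81).

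Other low genes were Tubb6, a beta-tubulin (-1.53), Ankrd37 (-1.11), Fos, an immediate early transcription factor (-1.02), Gm26532 (-0.97), Gm10076 (-0.92) and Ptpn22, a phosphatase of lymphocyte signalling (-0.88). Other high genes were Gm43305 (1.38), 4933406I18Rik (0.94), Crip2 (0.93), Bcl3, an atypical I-kappa-B protein (0.91), Cpt1a, the carnitine palmitoyltransferase of fatty acid oxidation (0.90), Gm5914 (0.89), Gadd45g (0.86), Lmna, the gene of lamin A and C (0.85), and Cirbp, a cold-inducible RNA-binding protein (0.85). Inflammatory NF-kB genes had a median of 0.42 (0.29 to 0.63), with 16 of 17 above 0 and Cxcl2 at 1.41. Cxcl2 was at only 7.99 and 21.2 CPM, and it is among the leading genes of the large-macrophage-like cluster 21. No macrophage profile was subtracted from B-like cells, so macrophage RNA was not told apart from their own. Antibody secretion genes had a median of -0.13, with Irf4 at -0.59, but -0.07 at resolution 2 and -0.07 (-0.19 to 0.02) thinned to equal depth, where no shift was detectable. Unfolded protein response genes had a median of -0.22. The resident macrophage list had a median of 0.92 in these cells.

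In B-intermediate cells the lowest genes were all among the lowest of B1-like cells, with Ly6k at -1.58, Tagap at -1.43, Myc at -1.34, Ankrd37 at -1.30 and Cd69 at -1.24. Among the highest named genes, Tppp3 was at 1.81, 4933406I18Rik at 1.39, Cpt1a at 1.37, Lmna at 1.23 and Marcksl1 at 1.20.

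In T-like cells the clearest differences were higher Ecm1, extracellular matrix protein 1, at 140 CPM in CD and 377 in HFD, a log2 ratio of 1.43 (1.29 to 1.57), and lower Tmem176a, 165 CPM in CD, at a log2 ratio of -2.12 (-2.38 to -1.86). Genes of naive T cells had a median of 0.28 (0.20 to 0.38), with 9 of 12 above 0, among them Igfbp4 (1.09), the chromatin organizer Satb1 (0.76), Dapl1 (0.59) and Lef1, a T-cell transcription factor (0.44). Further high genes were Patj (1.34), the junction adhesion gene Jaml (1.26), Gm15494 (1.23), Fam241a (1.20), Myo6, a myosin (1.15), Pdlim4 (1.15), Slc28a2b (1.12) and Klhdc2 (0.998). Without 2-lineage barcodes Satb1 was at 0.54, Dapl1 at 0.21, Lef1 at 0.09, Myo6 at 0.74 and Slc28a2b at 0.67. After subtraction of the B-like profile Ecm1 was at 1.16, Jaml at 0.96, Gm15494 at 1.03, Fam241a at 1.02 and Myo6 at 0.84. Pdlim4 was then at 0.84, Slc28a2b at 0.80, Igfbp4 at 0.78 and Klhdc2 at 0.76, while Patj was at 1.35 and Tmem176a at -2.45. The naive T-cell median was then 0.23. Tmem176a was at -1.37 thinned to equal depth and -3.38 with each library clustered alone. The make-up of the class also differed. Cluster 12, whose leading genes include Lef1, Dapl1, Igfbp4 and Myo6, held 15.3% of its barcodes in CD and 28.5% in HFD. Cluster 20, with Dapl1, Lef1 and Slc28a2b, held 9.47% and 13.7%. Clusters 9, 16 and 19 held 39.0%, 16.5% and 19.8% in CD and 35.3%, 20.2% and 2.35% in HFD. A different mix of clusters was not told apart from different expression within cells.

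T-cell activation, the main list here, had a median of 0.08 (-0.23 to 0.23), so no shift was detectable; it was -0.09 without 2-lineage barcodes and -0.18 after subtraction of the B-like profile. Among its members, Cd69 was at -1.38, Il2ra, the interleukin-2 receptor alpha chain, at -1.23, and Tnfrsf9, the costimulatory receptor 4-1BB, at 1.83. Cytotoxic genes had a median of 0.31 (0.09 to 0.39), with Gzmb at 1.75 and Gzmk at -0.52, but the median was -0.01 after subtraction of the B-like profile, 0.12 (-0.04 to 0.23) without 2-lineage barcodes and 0.07 (-0.11 to 0.16) with equal weight per barcode. Heat shock genes had a median of -0.26. B-cell RNA made up 25.5% of the UMIs of the class in CD and 7.0% in HFD, and 22.8% and 4.29% of barcodes carried a receptor contig, at median depths of 3650 and 4970 UMIs. The other 9 of the 10 lowest genes (Marchf1, Gm30211, Rnase6, Cyp4f18, Tnfrsf13c, Napsa, Ly86, Siglecg and Spib, from -2.59 to -2.03) were mostly B-like RNA in both libraries, and MHC class II genes had a median of -1.81, or -0.84 without 2-lineage barcodes.

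Receptors of B-1 type took larger shares in the HFD library. The pair IGHV11-2 with IGKV14-126 was carried by 6.55% of paired barcodes in CD (5.96 to 7.18) and 10.1% in HFD (9.12 to 11.2), and the pair IGHV12-3 with IGKV4-91 by 3.38% (2.96 to 3.85) and 5.98% (5.19 to 6.86). Both are known receptors of B-1 cells that bind phosphatidylcholine. IGHM, the constant region of IgM, was at 93.1% and 95.3%, a difference of 2.20 points (1.22 to 3.13), and IGHG3, of the IgG3 subclass, at 1.36% and 0.310%.

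With each clonotype counted once, chosen after the data were seen, the first pair was carried by 0.433% of clonotypes in CD and 1.12% in HFD and the second by 0.637% and 1.82%, differences of 0.69 and 1.18 points. In B1-like cells 24.8% of paired barcodes in CD and 32.1% in HFD carried these pairs; in B2-like cells it was 0 of 1282 and 0 of 918. IGHG2B was at 1.38% and 0.868%. The kappa share was 87.8% and 89.3%, but lower in HFD, by -0.14 points (-1.46 to 1.15), when the contig of most UMIs was taken. Among V genes, IGHV6-3 was at 5.02% and 2.73%, IGHV1-53 at 4.16% and 3.04%, IGHV1-55 at 3.53% and 5.61%, IGKV1-117 at 7.53% and 4.96%, IGKV1-110 at 6.27% and 4.43% and IGKV10-96 at 2.92% and 4.25%. For IGHV1-26, at 4.51% and 4.56%, no difference was detectable. With each clonotype counted once, the IGHV1-55 difference was 0.869 points (-0.064 to 1.89) and the IGKV1-110 difference -1.20 points (-2.35 to 0.030), and neither was detectable. The heavy CDR3 was 13.2 residues long on average in CD and 13.6 in HFD.

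Clonotypes of 2 or more barcodes held 47.3% of barcodes in HFD and 42.9% (41.2 to 44.4 over 1000 draws) in CD at equal numbers of 3225, and 57.0% in CD at its full number of 6536. With the clonotypes of the deposited tables the difference was smaller, at 2.56 points, and with heavy chains alone it was 4.00 points. By class, at full numbers, the shares in CD and HFD were 53.7% and 58.2% in B1-like cells, 24.8% and 19.0% in B2-like cells and 66.1% and 61.1% in B-intermediate cells. CD had more paired barcodes in each class, at 1398 against 1293, 1282 against 918 and 2043 against 535. The shares by class therefore do not compare clonality at equal numbers. In CD, barcodes of the same non-B class also shared clonotypes, with 66 macrophage-like pairs among clonotypes of 2 to 5 barcodes, against at most 9 in shuffles of the class names. The largest clonotype, of the IGHV11-2 with IGKV14-126 pair, held 208 barcodes in CD and 87 in HFD and was found in both libraries, as were 17 clonotypes in all. Of the barcodes in the receptor tables, 1952 in CD and 436 in HFD were not in the expression matrix, and paired barcodes outside the matrix had a median of 27 and 26 receptor UMIs, against 64 and 78 inside it. Those outside lay more often in clonotypes of 2 or more barcodes, at 74.0% against 53.0% in CD and 63.6% against 45.6% in HFD. Both kinds are in the whole-library clone measures above.

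**Figure D3:**
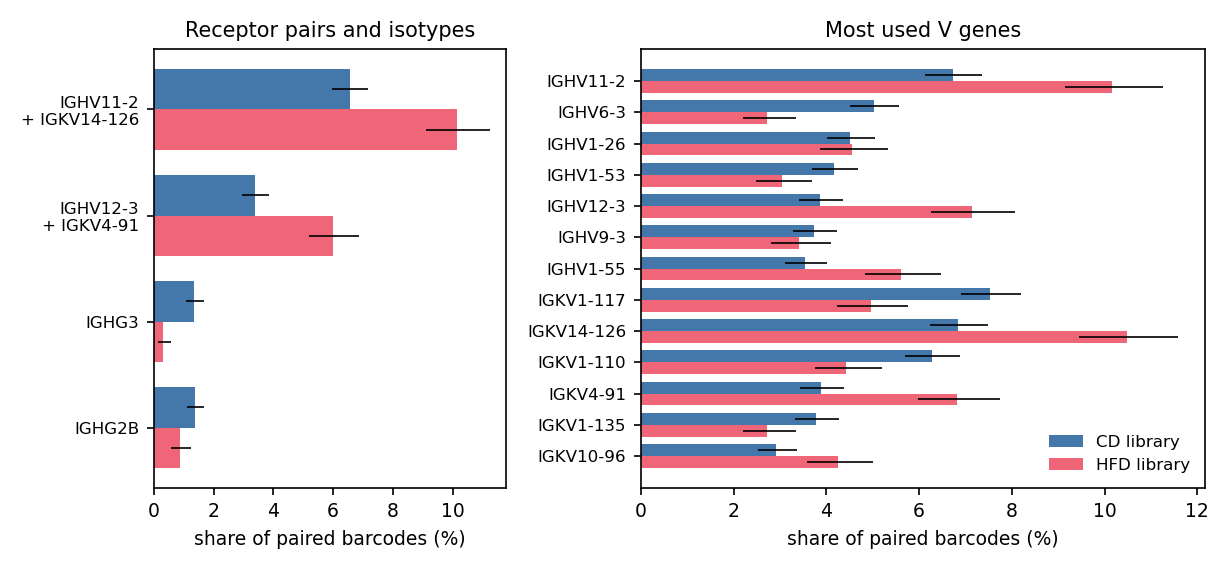
Share of barcodes with 1 heavy and 1 light contig (%) that carry the named receptor pairs, IgG constant regions and V genes in the CD and HFD libraries, with exact 95% binomial intervals that cover counting error only. IGHV11-2 with IGKV14-126 was at 6.55% in CD and 10.1% in HFD, and IGHG3 at 1.36% and 0.310%.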

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

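The removal of 2-lineage barcodes, the merged B class, the B-intermediate clusters given to the nearer side, the counting of each clonotype once and the subtraction of the B-like profile were chosen after the data were seen; all other settings were planned. No paired analysis was possible because each diet has 1 library and no label links the libraries. A change of direction was counted only for a result whose main interval left out 0. Over all settings, 988 values of named genes held 0 such changes, 820 list medians 11, 126 class shares 6 and 21 receptor shares 1. The named genes had been picked for their large ratios, so the 0 for them says little. Without such a change, 193 values of named genes, 123 list medians, 40 class shares and 3 receptor shares lay outside the main interval. The list and class pairs taken through the settings were narrowed after a first pass had shown some that changed direction; the values here are of the restored full set, with the pairs added in between. Depth limits which genes and list members pass the count minimums. Thinning to equal depth also left out shallower barcodes, with 11839 CD and 6303 HFD barcodes kept; the B1-like, B2-like and gamma-delta-T-like differences were then smaller and the large-macrophage-like difference larger, and the effects of depth and of the barcodes left out were not separated.

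The B1-like difference was 2.43 points at 200 genes and 20% mitochondrial UMIs, -3.32 at 800 genes and 5%, 15.3 with doublets kept, 13.5 and 8.63 at resolutions of 0.5 and 2, 25.7 with each library clustered alone and 1.55 thinned to equal depth. With the B-intermediate clusters given to the nearer side, the B1-like difference turned to -3.59 and the B2-like difference to -0.74. The B2-like difference was 2.25 at 800 genes and 5%, 5.28 clustered alone and 1.67 thinned. The large-macrophage-like difference was 6.49 at 200 genes and 20%, 7.10 thinned, and 6.46 and 6.52 without 2-lineage barcodes and also without mixed-lineage clusters; in the last 2 settings the T-like difference was 5.43 and 5.48, and it was 1.61 clustered alone. The small-macrophage-like difference turned to 0.13 at 200 genes and 20% and to 1.41 clustered alone, where the mixed-lineage difference turned to 1.02. The causes were not tested.

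In large-macrophage-like cells the lipid handling median was 0.19 at 200 genes and 20%, 0.025 clustered alone and -0.062 with the B-like profile subtracted, the inflammatory median was 0.25 thinned, the resident macrophage median turned to -0.058 with the profile subtracted, and the cytotoxic median to 0.35 clustered alone. In B1-like cells the antibody secretion median was -0.026 at resolution 2 and -0.029 thinned, the complement and coagulation median turned to -0.15 under both barcode filters and -0.16 thinned, the cytotoxic median to -0.0057 at 200 genes and 20% and -0.088 at 800 genes and 5%, and the regulatory and innate median to -0.011 clustered alone. In B2-like cells the naive T-cell median turned to -0.010 at 200 genes and 20%. In T-like cells the activation median was 0.25 at resolution 0.5 and the cytotoxic median turned to -0.0065 with the profile subtracted. The kappa difference turned to -0.14 with the contig of most UMIs. In B1-like and B2-like cells alone the difference in shared clonotypes was 9.21 points. With each clonotype counted once, the differences of the IGHV11-2 and IGHV12-3 pairs were 0.69 and 1.18. The causes were not tested.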

Other observations

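All tests below were chosen or put in their final form after other results had been seen. Only for the split of macrophage-like clusters, at equal depth and without 2-lineage barcodes, were the bounds written before the values existed.

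The unnamed macrophage cluster had the same chemokines at its upper end as the large-macrophage-like cells. Its leading genes include the small-macrophage markers Folr2 and Retnla and the large-macrophage marker Fcna. Klk8 was at 5.07 CPM in CD and 75.6 in HFD, a log2 ratio of 3.90 (3.18 to 4.71), Ccl2 at 3.01, Ccl7 at 2.08, Car6 at 2.10 and Gpx3, a secreted glutathione peroxidase, at 2.71. Its lowest genes were Fcrla (-2.60), Ets1 (-2.57), Gm30211 (-2.43), Cd79b (-2.35) and Cd79a (-2.34), of which the last pair form the B-cell receptor complex. Receptor contigs were found on 20.2% of its CD and 6.41% of its HFD barcodes, and 2-lineage barcodes were 30.9% and 7.69%.

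The large-macrophage-like cells lay in different clusters in the 2 libraries: clusters 5, 21 and 23 held 93.3% of this class in HFD and 3.87% in CD, a gap of 89.4 points. Depth per barcode and 2-lineage barcodes do not account for this split: with clusters drawn anew the gap was 87.0 points at equal depth and 81.7 points without 2-lineage barcodes, each above the bound of 80. Free RNA of B cells may account for a part and stays undecided. Of 124 differing genes, 41 had 50% or more of their CPM from a B-like profile, and no ratio was taken for them after its subtraction. The other 83 all kept at least 50% of their log2 ratio. The 83 are 66.9% of the 124, between the bounds of 50 and 80. For genes of large ratio the limit on CPM by itself fixes that they keep it. The 83 therefore mainly count genes that were not mostly B-like RNA. Ets1, Fcrla and Acp5, 3 named genes, were mostly B-like RNA in CD. These tests replaced counts of the 20 named genes, which had been picked for their ratios and whose results had been seen. Of them, 20 kept their direction at equal depth and 20 without 2-lineage barcodes. After subtraction 17 did, with the 3 mostly B-like genes left out, which the same limit on CPM fixed in advance. A difference between the preparations of the 2 libraries cannot be told apart from diet, since each diet has 1 library, and diet itself was not tested.

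MHC class II genes were lower in macrophage-like and T-like cells of the HFD library, and RNA of B cells may account for this. A first test took the list median after subtraction of a B-like profile, with each gene held at or above 3 counts. In T-like cells it gave 0.06 (-0.05 to 0.39), with 7 of 11 genes at that floor. In macrophage-like cells it gave -0.45 (-0.45 to -0.44), with 4 of 11 at the floor, which met neither bound written for it. Each median was the value of a gene at the floor in both libraries, which depends only on the UMI totals of the class. The first test therefore cannot decide in either class. A second test, written after that result, took the share of each gene's fall that the profile brings: a median of 102% (96.4 to 109) in T-like cells and 101% (96.5 to 107) in macrophage-like cells. Only the second test is informative, and it points to B-cell RNA in T-like cells. In macrophage-like cells its median was about as high, but a smaller fall in the macrophages' own transcripts stays open. There 8 of 11 members were mostly B-like RNA, and the median of the others after subtraction was -0.17. Ctss, a lysosomal protease gene, had 10.3% of its fall accounted for. In the unnamed macrophage cluster all 11 members were lower too, with a median of -1.225 (-1.28 to -1.14), or -1.19 without 2-lineage barcodes. The profile was not subtracted in that cluster, so the part of B-cell RNA there was not tested.

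In the CD library, T-like barcodes often shared a B-cell receptor with other T-like barcodes, and macrophage-like barcodes with other macrophage-like barcodes. Among clonotypes of 2 to 5 barcodes, 66 pairs of macrophage-like barcodes had the same clonotype, against at most 9 in 1000 shuffles of the class names, which argues against chance capture of B cells or of their free RNA; T-like barcodes gave 50 pairs against at most 6. In HFD the counts were 3 and 1, against at most 2 and 1. A candidate explanation is that the content of 1 droplet was counted under several barcodes: in rare genes seldom found in B-like cells, 10.6% (4.37 to 20.6) of the 66 pairs were more alike than the 99th percentile of random pairs of receptor-bearing barcodes. An earlier form, with random pairs of the whole class, was set aside after its result was seen, same-clonotype pairs of B2-like barcodes were also more alike than that percentile in rare genes (18.6%), and no biological explanation was tested.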
